A study of Mus musculus with 8 samples.

How the data were processed

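RNA sequencing was done on c-kit+ acute myeloid leukaemia cells from mouse bone marrow, in 8 libraries that fall into 4 groups of 2. The groups combine 2 Ezh1 genotypes with corn oil or tamoxifen, and tamoxifen marks deletion of a floxed Ezh2. Per the labels, tamoxifen was given in corn oil at 10 mg/kg/day for 5 doses by intraperitoneal injection, cells were taken 7 days after treatment, and TruSeq libraries were made from 1 µg of total RNA. Each library was placed in its group by the genotype and treatment in its label, and its replicate number was taken from its title. The labels do not say that replicates are separate animals or separate leukaemias, so every p measures the spread between these libraries. Tamoxifen and Ezh2 deletion go together in every library, and each Ezh1 genotype may come from its own leukaemia, so neither pair of factors can be separated here.

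Both deposited tables are fold-change lists that the authors exported from a gene-level analysis program, after a filter to the 20th to 100th percentile of the raw data per the file headers. Per the file headers the values per library are normalized, and in both deposited tables they proved to be log2 of a normalized read count with a floor of 1, centred on the gene's median over the 8 libraries. The largest absolute row median was 9.55e-07, and each log2 fold change that the authors deposited equalled the difference of the group means of these columns to within 5.4e-07. The deposited tables also give that change as an absolute ratio (fold change) and as a signed fold change, where a fall is minus the inverse ratio. The larger table holds 31574 rows, and the smaller holds the 4576 of these with a deposited fold change of at least 2 in either tamoxifen comparison, with identical values. The p values here are all computed from these columns. The genome build is mm10 per the labels, and gene identifiers, symbols and coordinates are those of the deposited tables. The aligner, the read counter and the scaling factors are not given in the sources used here.

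Centring removes the level of a gene, except where libraries lie at the floor. A floor was identified where at least 2 libraries tied at the lowest value of a row, to a tolerance of 2e-06. Among low rows of this kind, 68.1% to 80.5% of the values above the floor in a library lay within 0.01 of a whole number of reads, at the normalized value of 1 read found for that library. That value is used as a rough measure of relative depth. It ran from 0.746 in Ezh1-present tamoxifen replicate 1, the deepest library, to 1.24 in Ezh1-null oil replicate 1. Total counts cannot be recovered, since whole reads fitted only 27 of 300 rows searched, so no test on counts was made. Where every library of a group lay at the floor, folds are given as lower limits against 3 reads per library. These limits cover counting error only. Libraries at the floor cannot vary, which lowers the fitted spread of such genes and can make their p too small.

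The values were analysed with limma 3.58.1 in R 4.3.3, with tables handled in pandas 2.3.3 under Python 3.11.15 and plots drawn with matplotlib 3.10.9. The fit held all 8 libraries with 1 coefficient per group and no block, and empirical Bayes moderation without a trend. It used the 18051 rows with at least 2 libraries above the floor, and left out 12530 rows with every library at the floor and 993 with 1 library above it. The residual degrees of freedom were 4 and the prior degrees of freedom 1.24. A gene was called where its Benjamini-Hochberg adjusted p lay under 0.05. The plan made before the data were examined had foreseen counts, or normalized values with a known level and a trend of the variance on that level. Since the level is removed, the fit without a trend took its place and the trend became an alternative. The comparisons were tamoxifen minus oil in each Ezh1 genotype, Ezh1-null minus Ezh1-present in oil and in tamoxifen libraries, and the difference between the tamoxifen changes (the interaction). With 2 libraries against 2, the smallest exact two-sided permutation p is 0.333, so no gene was tested by permutation.

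Gene lists (31 of them) were fixed before the data were examined, and the 29 with at least 3 measured members were tested with camera at a preset correlation of 0.01, adjusted over lists within a comparison. The same test with a correlation estimated per list, and fry, stand beside it. The estimated form also refers each list to the 4 residual degrees of freedom, so it can lose calls whatever the correlation. The genes named were chosen by a rule fixed at the same time. It took Ezh1 and Ezh2, then the 8 largest rises and 8 largest falls among called genes whose groups do not overlap and whose higher group mean lies above the median (5 and 5 for the interaction, overlap allowed). It also took up to 4 members of each called list and up to 3 called members of any list with the smallest p, and called CDK inhibitors and D-type cyclins with their kinases. Since the values are centred, the condition on the higher mean favours large deviations from a gene's own median. It does not select by level, so genes named by size can lie near the floor. Predicted genes, Rik clones, receptor segments and microRNAs were passed over among the largest changes, and the text gives a selection of the list members. A few genes that the rule or a list names are not reported here.

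The pipeline was tested on simulated data with 18051 genes, of which 200 were changed between the Ezh1-null groups. It recovered 25.4% of genes changed by 1 on the log2 scale, 61.2% at 2 and 78.8% at 3, with 9 false calls. The list made to shift was called, and 0 of 28 other lists were called by camera. Simulated genes varied independently and had no floor, so this says nothing of false list calls where members vary together. In the real data the estimated correlation was 0.91 for the erythroid list. Alternatives covered quantile normalization, a looser and a stricter filter, robust moderation, a replicate block, fits of only the groups compared, and leaving out each library in turn. A fit with library medians set to 0, a trend on the row mean, rows without an identified floor, and leaving out Ezh1-present oil replicate 1 together with Ezh1-present tamoxifen replicate 2 were added after the data were seen. Quantile normalization and the trend acted on the centred values, whose row mean is not the level of a gene. Calls that they gained or lost are to be read with that limit.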

Results

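The data are gene-level RNA sequencing values of c-kit+ acute myeloid leukaemia cells from mice of the C57BL/6 strain. Of the 8 libraries, 2 came from Ezh1-present cells after oil, 2 from Ezh1-present cells after tamoxifen, 2 from Ezh1-null cells after oil and 2 from Ezh1-null cells after tamoxifen. Tamoxifen marks deletion of Ezh2. Ezh1 and Ezh2 are the alternative methyltransferase subunits of Polycomb repressive complex 2 (PRC2), which silences genes. The median SD between the libraries of a group was 0.116 in Ezh1-present oil, 0.128 in Ezh1-present tamoxifen, 0.117 in Ezh1-null oil and 0.107 in Ezh1-null tamoxifen, on the log2 scale. All group values are log2 values relative to the gene's own median over the 8 libraries, given as mean ± SD with n = 2. Log2 changes are given ± the standard error of the limma fit, with 2 libraries per group.

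The targeted genes come first. Ezh1 (gene 14055, mm10 chromosome 11, 101191115 to 101226450) lay at 1.68 ± 0.04 in Ezh1-present oil, 1.59 ± 0.06 in Ezh1-present tamoxifen, -1.84 ± 0.14 in Ezh1-null oil and -1.58 ± 0.05 in Ezh1-null tamoxifen libraries. It fell with Ezh1 loss, with log2 changes of -3.53 ± 0.10 in oil (adjusted p = 0.00108) and -3.17 ± 0.10 after tamoxifen (adjusted p = 0.000793). Ezh2 (gene 14056, chromosome 6, 47530274 to 47595338) lay at 0.24 ± 0.02, 0.06 ± 0.05, -0.07 ± 0.07 and -0.54 ± 0.02 in the same order of groups. Its log2 change after tamoxifen was -0.18 ± 0.08 with Ezh1 present (adjusted p = 0.293) and -0.47 ± 0.08 without Ezh1 (adjusted p = 0.0554), and neither passed the threshold. Ezh2 was lower in Ezh1-null than in Ezh1-present cells by a log2 change of -0.31 ± 0.08 in oil (adjusted p = 0.0492) and -0.60 ± 0.08 after tamoxifen (adjusted p = 0.02). Over the 18 alternatives the adjusted p for Ezh2 ranged from 0.0283 to 0.205 for tamoxifen without Ezh1, from 0.0347 to 0.164 for Ezh1 loss in oil and from 0.00909 to 0.0894 for Ezh1 loss after tamoxifen. The oil call for Ezh2 ended without any 1 of the 8 libraries, at adjusted p of 0.159 without Ezh1-present oil replicate 1, 0.13 without replicate 2, 0.0629 without either Ezh1-present tamoxifen library, 0.164 without Ezh1-null oil replicate 1, 0.106 without replicate 2 and 0.0829 without either Ezh1-null tamoxifen library. The tamoxifen call for Ezh2 ended at 0.0677 without Ezh1-present tamoxifen replicate 1, 0.0564 without replicate 2, 0.0826 without Ezh1-null tamoxifen replicate 1 and 0.0822 without replicate 2. Values summed over a gene do not resolve the deleted exons, and reads from the rest of the transcript can remain.

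**Figure D1:**
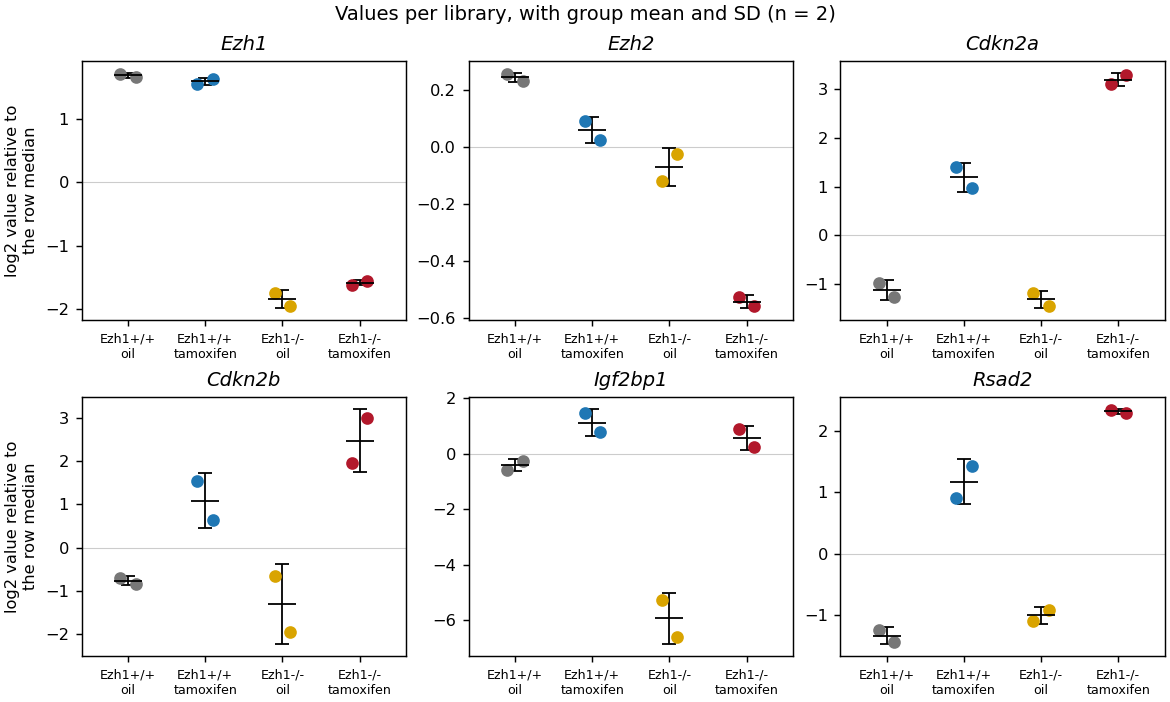
Log2 value relative to the row median (vertical axes) of 6 genes in each of the 8 libraries, by genotype and treatment. Points are libraries and bars are group mean and SD with n = 2. Ezh1 lies at -1.84 and -1.58 in the Ezh1-null groups, and Cdkn2a reaches 3.19 in Ezh1-null tamoxifen libraries.

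The first comparison asks what deletion of Ezh2 does to leukaemia cells that keep Ezh1. Cdkn2a, which encodes the tumour suppressors Ink4a and Arf, was 4.94-fold higher after tamoxifen (log2 change 2.31 ± 0.20, adjusted p = 0.0276). Bmi1, a subunit of Polycomb repressive complex 1, rose by 1.13 ± 0.11 (adjusted p = 0.0284). The largest rises by the naming rule were in Myct1 (5.16 ± 0.61), in Klrd1, an NK cell receptor (5.09 ± 0.47), in Lin28b, an RNA-binding protein of fetal blood stem cells (4.92 ± 0.59), and in Nkg7, a protein of cytotoxic granules (4.79 ± 0.57). Morc4, Prrg4, Eya1 and Ppic followed at 3.99 to 4.17. The largest falls were smaller, with log2 changes of -2.18 ± 0.23 for the chloride channel Clcn1, -2.12 ± 0.20 for Bdkrb1 and -2.12 ± 0.26 for Cts8. Wnt7a, Tas2r135, Mapk10, Olfr1061 and Emx2os also fell, to the floor in both tamoxifen libraries, by at least 1.64-fold for Wnt7a and at least 1.16-fold to 1.25-fold for Mapk10, Olfr1061 and Emx2os.

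Of 18051 genes, 163 were called, 115 higher and 48 lower, and 36 of these had a group wholly at the floor. The groups did not overlap in 53.8% of genes, where chance gives 33.3%. The count moved when any 1 library was left out, also a library of the Ezh1-null groups, which are not compared here. An Ezh1-null library left out cannot change these fold changes. It acts only through the fitted spread of each gene, with 3 residual degrees of freedom in place of 4. With Ezh1-present oil replicate 1 and tamoxifen replicate 2 both left out, and with only the Ezh1-present groups in the fit, limma called 0 genes, with 1914 and 3152 genes at an unadjusted p under 0.05. Mapk10 and Olfr1061 were the genes among the 17 named by size or as CDK inhibitors that stayed called without any 1 library, and neither stayed called with quantile normalization or with only the Ezh1-present groups in the fit (highest adjusted p 0.154 and 0.162). Both lie at the floor in both Ezh1-present tamoxifen libraries, which cannot vary there, so these calls may owe their stability to the floor. Of the 8 fits that leave out 1 library, Cdkn2a stayed called in the fit without Ezh1-present tamoxifen replicate 1 (adjusted p = 0.034). Its adjusted p was 0.115 and 0.082 without Ezh1-present oil replicates 1 and 2, 0.051 without Ezh1-present tamoxifen replicate 2, 0.0681 without either Ezh1-null oil library and 0.0768 without either Ezh1-null tamoxifen library, and it ranged from 0.0275 to 0.162 over 18 alternatives.

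Among the gene lists, genes induced by interferon rose together in Ezh1-present cells after tamoxifen. Of 25 members, 24 had a positive change and 4 were called, with a median of 1.24; adjusted over the list alone, 20 were higher and 1 lower. The called members were Rtp4 (3.87 ± 0.40), the antiviral protein Rsad2 (2.50 ± 0.20), Ifi27l2a (1.90 ± 0.19) and Oas3 (1.39 ± 0.17). The list passed camera (adjusted p = 1.36e-11), with adjusted p = 0.558 with an estimated correlation. Cholesterol synthesis genes rose slightly, with 20 of 20 changes above 0, a median of 0.30 and 0 members called (3 higher, adjusted over the list alone), at camera adjusted p = 3.46e-05 and adjusted p = 0.558 with an estimated correlation. Adjusted over all genes, limma had called 0 of them among the 3713 genes of this comparison at an unadjusted p under 0.05.

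Of the 14 lists called in this comparison, several hold markers of other marrow cells. The lists of T and NK cell genes (median 1.98, camera adjusted p = 3.88e-07), erythroid genes (3.35, 0.000167), mature neutrophil genes (1.63, 0.000193) and megakaryocyte and platelet genes (1.53, 0.00107) rose, each with adjusted p = 0.558 with an estimated correlation and with 0 members called by limma over all genes. Adjusted over the list alone, 14 T and NK, 6 erythroid, 0 neutrophil and 5 megakaryocyte genes were higher. The medians leaned on 1 library: without Ezh1-present tamoxifen replicate 2 they were 1.67 for T and NK, 1.67 for erythroid, 1.10 for neutrophil and 0.94 for megakaryocyte genes.

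Further lists passed camera upwards with Ezh1 present, each with adjusted p = 0.558 with an estimated correlation. They were mast cell, basophil and eosinophil genes (median 2.59, adjusted p = 0.00271), stromal and endothelial genes (1.29, 0.00901), primary granule genes (0.53, 0.0117), monocyte and macrophage genes (0.22, 0.0141) and stem and progenitor cell genes (1.22, 0.0221). Mitosis and G2/M genes passed as well (0.25, 0.00362, and adjusted p = 0.608 with an estimated correlation). Over all genes limma called 1 primary granule gene, 2 monocyte genes and 0 members of the others, against 3713 genes of the comparison at an unadjusted p under 0.05. The called member of the primary granule list was Nkg7, named above as a protein of cytotoxic granules. Adjusted over the list alone, 7 mast cell genes were higher and 1 lower, 0 stromal, 6 and 2 primary granule, 9 and 1 monocyte, 11 and 2 stem cell, and 0 mitosis genes. Each of these calls ended without 1 library. Adjusted p was 0.0535 without Ezh1-present tamoxifen replicate 2 for mast cell (median 1.56) and for stem cell genes (0.79), and 0.0708 without Ezh1-present tamoxifen replicate 1 for primary granule and for monocyte genes. Without Ezh1-present oil replicate 2 it was 0.0674 for stromal, 0.0524 for stem cell and 0.0517 for monocyte genes, and without Ezh1-present oil replicate 1 it was 0.114 for the list of mitosis and G2/M genes (median 0.12). Medians also moved to 0.82 for stromal and endothelial genes and 0.54 for monocyte and macrophage genes without Ezh1-present tamoxifen replicate 2, to 0.63 for the latter without Ezh1-present oil replicate 1, and to 0.38 for mitosis genes without Ezh1-present oil replicate 2.

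The Hoxb, Hoxc and Hoxd clusters, which pattern the embryo, rose with a median of 0.55, or 0.29 with the 6 members at the floor set to their bound. Their called members were Hoxb3 (1.46 ± 0.17) and Hoxb5 (3.35 ± 0.42), and 5 were higher adjusted over the list alone. This list had camera adjusted p = 0.0153, adjusted p = 0.558 with an estimated correlation, and 0.0615 without Ezh1-present oil replicate 2. Without Ezh1-present tamoxifen replicate 1 the median of this Hox list was 1.01. The list of Hoxa cluster, Meis and Pbx genes, regulators of blood stem cells, fell with a median of -0.41 and 3 of 16 changes above 0, at camera adjusted p = 0.0487 and adjusted p = 0.558 with an estimated correlation. Over all genes limma called 0 of its members, and adjusted over the list alone 1 was higher and 1 lower. Its call ended at 0.253 without Ezh1-present oil replicate 1 (median -0.22) and 0.197 without Ezh1-present tamoxifen replicate 2 (median -0.25), with a range of 0.0097 to 0.665 over the alternatives at the preset correlation.

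**Figure D2:**
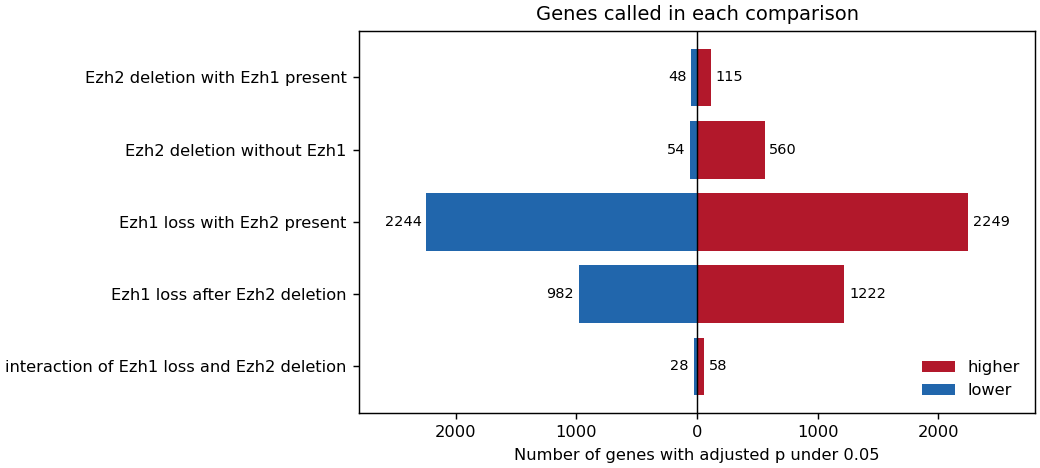
Number of genes with adjusted p under 0.05 (horizontal axis) in each comparison, higher to the right and lower to the left. Ezh2 deletion gave 163 calls with Ezh1 present and 614 without Ezh1, and Ezh1 loss gave 4493 and 2204.

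The next comparison asks what deletion of Ezh2 does to cells that already lack Ezh1, with tamoxifen as its marker. Cdkn2a (gene 12578, chromosome 4, 89274473 to 89294619) was 22.7-fold higher, from -1.31 ± 0.18 to 3.19 ± 0.14 (log2 change 4.51 ± 0.20, adjusted p = 0.00264). Its neighbour Cdkn2b, which encodes the CDK inhibitor Ink4b (gene 12579, chromosome 4, 89306289 to 89311032), was 13.7-fold higher (3.77 ± 0.59, adjusted p = 0.0406). Ccnd1, which encodes cyclin D1 (gene 12443, chromosome 7, 144929931 to 144939925), was 4.06-fold higher (2.02 ± 0.27, adjusted p = 0.0284). Of 10 fetal programme genes 3 rose, over all genes and adjusted over the list alone: the RNA-binding protein Igf2bp1 by 6.50 ± 0.51 (90.2-fold, adjusted p = 0.00792), Lin28b by 5.43 ± 0.59 and the growth factor Igf2 by 2.59 ± 0.33. The fetal list as a whole did not pass (median 0.62, or 0.10 with 1 member at its bound, camera adjusted p = 0.0526, and adjusted p = 0.385 with an estimated correlation). Igf2bp1 lay at -5.93 ± 0.93 in Ezh1-null oil and 0.57 ± 0.44 in Ezh1-null tamoxifen libraries, against -0.41 ± 0.23 in Ezh1-present oil, so it had been lower in Ezh1-null cells before.

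Other large rises were in Ear6, an eosinophil ribonuclease (6.69 ± 0.84), Scara3 (6.13 ± 0.64), the germ line regulator Dmrt1 (6.05 ± 0.55) and Fgf3 (5.90 ± 0.98). Zic1, the Wnt antagonist Sfrp2 and Chn1 came up from the floor in both oil libraries, by at least 22.3-fold, 21.7-fold and 15.4-fold. The falls were fewer and smaller. Fbxw15 fell by at least 2.44-fold and the complement receptor Cr2 by at least 1.71-fold, both to the floor, and the cytokine Il4 changed by -1.81 ± 0.26. The log2 changes of Slc38a8, Il17re, G6pc and Pom121l2 were between -2.50 and -1.41.

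In total 614 genes were called, 560 higher (91.2%) and 54 lower, and 104 of these had a group wholly at the floor. Quantile normalization gave 342 higher (74.8%) and 115 lower, with 377 genes in common. The authors' own table lists 2301 rows at least 2-fold higher and 501 lower without Ezh1, and 1949 higher and 905 lower with Ezh1 present, without a test. The count was 393 without either Ezh1-present oil library, 368 without Ezh1-null oil replicate 1, 286 without replicate 2, 213 without Ezh1-null tamoxifen replicate 1 and 176 without replicate 2, and 240 with only the Ezh1-null groups in the fit. Of the 19 genes named by size or as cell cycle genes, Cdkn2a, Igf2bp1, Sfrp2, Chn1 and Rxfp1 stayed called without any 1 library. Of these, 3 (Cdkn2a, Sfrp2 and Rxfp1) also did under every other alternative that gave a value. Rxfp1 gave a value in 16 alternatives and Sfrp2 in 17, against 18 for Cdkn2a, since both have libraries at the floor. Their calls, and that of Chn1, may owe their stability to the floor. With a trend the adjusted p was 0.345 for Igf2bp1 and 0.783 for Chn1, and with only the Ezh1-null groups it was 0.086 for Igf2bp1. Over all alternatives it ranged from 0.00757 to 0.345 for Igf2bp1 and from 0.00436 to 0.783 for Chn1. Cdkn2b lost its call without each of the 8 libraries, and without any 1 Ezh1-present library its log2 change stayed at 3.77. Its adjusted p was 0.0926 without either Ezh1-present oil library, 0.0738 without either Ezh1-present tamoxifen library, 0.0547 and 0.118 without Ezh1-null oil replicates 1 and 2, and 0.103 and 0.164 without Ezh1-null tamoxifen replicates 1 and 2. For Ccnd1 it was 0.067 without either Ezh1-present oil library, 0.098 and 0.114 without Ezh1-null oil replicates 1 and 2, and 0.105 and 0.135 without Ezh1-null tamoxifen replicates 1 and 2. The log2 changes over these fits were 3.12 to 4.43 for Cdkn2b and 1.88 to 2.17 for Ccnd1.

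The list of interferon response genes also rose in this comparison. Of its 25 members 14 rose and 11 did not pass, with a median of 2.10; 22 were higher adjusted over the list alone. Rsad2 rose by 3.33 ± 0.20, Oasl2 by 3.28 ± 0.28, Ifi27l2a by 2.91 ± 0.19 and Oas3 by 1.98 ± 0.17. The list had camera adjusted p = 2.38e-17 and adjusted p = 0.349 with an estimated correlation. MHC class I and antigen processing genes, which include many targets of interferon, rose with a median of 0.44 (camera adjusted p = 5.93e-05, adjusted p = 0.542 with an estimated correlation). Their called member was B2m, the light chain of MHC class I (0.59 ± 0.09), and 6 of 16 were higher adjusted over the list alone. The MHC class I median was 0.67 without Ezh1-null oil replicate 1 and 0.27 without replicate 2.

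Targets of the tumour suppressor p53 rose as a list, with a median of 0.85 over 17 members, or 0.80 with 1 member at its bound. Of these, 5 were called and 14 were higher adjusted over the list alone, at camera adjusted p = 7.35e-10 and adjusted p = 0.061 with an estimated correlation. Examples are Zmat3 (3.26 ± 0.28), the apoptosis genes Bbc3 (1.25 ± 0.10) and Pmaip1 (0.71 ± 0.10), and the stress response gene Sesn2 (0.90 ± 0.10). In oil the same p53 target genes had been lower in Ezh1-null than in Ezh1-present cells, with a median of -0.40, or -0.38 with 1 member at its bound, and 5 lower and 1 higher (5 and 1 adjusted over the list alone). That difference had camera adjusted p = 0.0391 and adjusted p = 0.653 with an estimated correlation, and ended at 0.0649 without Ezh1-present oil replicate 2 (median -0.25), 0.0628 without either Ezh1-present tamoxifen library, and 0.104 without Ezh1-null oil replicate 2, in a range of 0.0278 to 0.104 over the alternatives at the preset correlation. After tamoxifen the p53 list did not pass between the Ezh1 genotypes (median 0.23, camera adjusted p = 0.092). DNA replication and G1/S genes fell by a small amount, with 22 of 23 changes below 0 and a median of -0.26. Mcm6, a subunit of the replicative helicase, was the called member (-0.48 ± 0.08), and 2 were lower adjusted over the list alone. This list had camera adjusted p = 8.83e-08 and adjusted p = 0.319 with an estimated correlation.

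Developmental genes that Polycomb occupies in stem cells also rose as a list. Of 46 measured, 6 were called and 10 were higher adjusted over the list alone. The median was 1.05, and 0.08 with the 26 members at the floor set to their bound (camera adjusted p = 8.07e-05, adjusted p = 0.385 with an estimated correlation). It was 0.68 without Ezh1-null oil replicate 1. Tbx15 rose by 4.64 ± 0.45, while Otx2 and Zic2 were at least 3.99-fold and 2.95-fold higher from the floor. The Hoxb, Hoxc and Hoxd clusters had a median of 0.84, of 0.00 with 12 members at their bound, and of 0.44 without Ezh1-null tamoxifen replicate 2. Their 4 called members were Hoxc4, Hoxc9 and Hoxc5, at least 13.2-fold, 4.87-fold and 4.81-fold higher, and Hoxb13 (3.83 ± 0.50), and 6 were higher adjusted over the list alone. This list had camera adjusted p = 0.000454 and adjusted p = 0.385 with an estimated correlation. The T and NK cell list, a marker of other marrow cells, moved up with a median of 0.95 and 0 members called by limma, also adjusted over the list alone. Its camera adjusted p was 0.0403 (0.714 with an estimated correlation), and 0.188 without Ezh1-null oil replicate 2, 0.0839 and 0.0616 without Ezh1-null tamoxifen replicates 1 and 2. The unadjusted p lay under 0.05 for 3223 genes of the whole comparison.

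**Figure D3:**
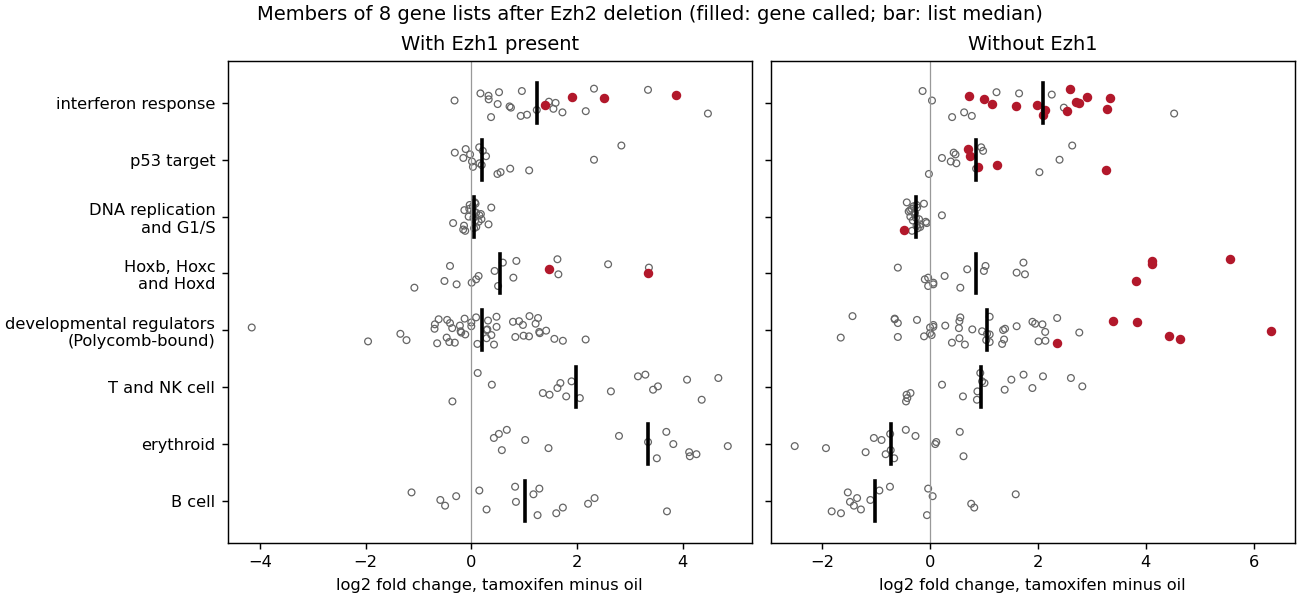
Log2 change after Ezh2 deletion (horizontal axes) of the members of 8 gene lists, with Ezh1 present on the left and without Ezh1 on the right. Circles are genes, filled where called, and bars are list medians. Members at the floor are drawn at their fitted change. The interferon response list has medians of 1.24 and 2.10.

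The changes after Ezh2 deletion in the 2 Ezh1 genotypes were compared over sets of libraries that share none. Of genes called higher, 40 were shared where chance gives 3.57 (Fisher's exact test, p = 1.97e-31), and 433 of the 560 called without Ezh1 (77.3%) also had a positive change with Ezh1 present. Of genes called lower, 2 were shared, where chance gives 0.14, but 28 of the 54 called without Ezh1 (51.9%) had a negative change with Ezh1 present, with a median of -0.01 there. Both sets of calls use the same fitted spread per gene, so genes of low spread can be called in both. The chance values and the p do not allow for this. Across genes, which are not independent replicates, Pearson's r between the changes was 0.26. Cdkn2a and Bmi1 rose in both genotypes. For Cdkn2a the change without Ezh1 exceeded that with Ezh1 by 2.20 ± 0.28 on the log2 scale, at an adjusted p of 0.0663 for the interaction, and for Igf2bp1 by 4.96 ± 0.73 (adjusted p = 0.0784). Neither passed the threshold.

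The interaction passed for 86 genes, 58 with a more positive and 28 with a more negative change without Ezh1. Of the 58, 46 were also called higher without Ezh1. Quantile normalization gave 37 genes, 20 more positive and 17 more negative. The naming rule picked the collagen gene Col13a1 (adjusted p = 0.0105), Chn1, the carbonic anhydrase relative Car11, C2cd4c and the developmental regulator Otx2 among positive differences. Both Ezh1-null oil libraries lie at the floor in these 5 genes, so their fitted differences are not measured sizes. Their p can be too small, since libraries at the floor cannot vary. Among negative differences it picked Dntt, the terminal transferase of lymphoid progenitors (-5.21 ± 0.48, adjusted p = 0.0373), Rnase10 (-4.39 ± 0.49) and Il17re (-3.13 ± 0.33), and Il4 and Gpr44, which have a group at the floor. The count rests on low values in part, since 54 of the 86 had a group wholly at the floor. Of the 86, 31 have no identified floor, while a fit of only such rows called 6. The cause of that drop was not tested. The count was 17 without Ezh1-present oil replicate 1, 24 and 48 without Ezh1-null oil replicates 1 and 2, and 41 and 34 without Ezh1-null tamoxifen replicates 1 and 2. With Ezh1-present oil replicate 1 and tamoxifen replicate 2 both left out, limma called 0 genes, with 1857 at an unadjusted p under 0.05. Each of the 10 named genes lost its call without at least 1 library.

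Lists that passed for the interaction included p53 targets, whose change was more positive without Ezh1 (median difference 0.50, camera adjusted p = 3.04e-05, adjusted p = 0.214 with an estimated correlation). DNA replication and G1/S genes had a more negative change (-0.30, camera adjusted p = 6.94e-06, adjusted p = 0.447 with an estimated correlation), as had erythroid genes (-3.23, camera adjusted p = 9.32e-06, adjusted p = 0.578 with an estimated correlation). Over all genes limma called 0 members of these 3 lists, where 2697 genes of the interaction had an unadjusted p under 0.05. Adjusted over the list alone, 4 p53 targets were more positive and 1 erythroid gene more negative. The erythroid median was -1.94 without Ezh1-present tamoxifen replicate 2. For the interferon response list the difference was 0.66 (camera adjusted p = 0.00168, adjusted p = 0.613 with an estimated correlation), and its call ended at 0.0753 without Ezh1-present tamoxifen replicate 1.

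The third question is how Ezh1-null leukaemia cells differ from Ezh1-present ones while Ezh2 is intact. Some of the highest rises in Ezh1-null oil libraries were in genes that early B cells use: the recombinase gene Rag1 by at least 523-fold, Dntt by 8.63 ± 0.34, the B lineage regulator Ebf1 by 7.85 ± 0.60 and the surrogate light chain Vpreb1 by 6.82 ± 0.42 on the log2 scale. The granule genes Elane (5.74 ± 0.42) and Mpo (1.97 ± 0.17), the IgE receptor chain Ms4a2 (8.11 ± 1.03) and the basophil protease Prss34 (7.26 ± 0.72) were also higher. Of 16 B cell genes 9 were called and of 13 mast cell, basophil and eosinophil genes 5 (9 and 6 adjusted over the list alone), at camera adjusted p = 0.000671 and 0.00229, and adjusted p = 0.86 with an estimated correlation for both. Stfa2 and Stfa2l1, stefin A genes, rose by 8.77 ± 0.85 and 8.23 ± 1.00, and Prdm16, a regulator of blood stem cells, by 7.60 ± 0.92. The homeobox gene Nkx6-2 (-7.67 ± 0.49), the imprinted transcripts H19 (-7.50 ± 0.78) and Igf2 (-3.54 ± 0.33), Igf2bp1 (-5.52 ± 0.51) and Hoxb13 (-5.24 ± 0.50) fell. Ccdc36 was at least 15.6-fold lower, and Matn1, Ttll6, Ncmap and Neurl1a changed by -5.44 to -5.22.

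Here 4493 genes were called, 2249 higher and 2244 lower, and 238 of these had a group wholly at the floor. The groups did not overlap in 65.8% of genes, where chance gives 33.3%. The count was 1707 and 2183 without Ezh1-present oil replicates 1 and 2, 2658 and 1925 without Ezh1-null oil replicates 1 and 2, and 2531 with only the oil groups in the fit. Of the 20 genes named by size or as CDK inhibitors, 17 stayed called without any 1 library, and the exceptions were Cdkn1b, Cdkn1a and Cdkn2d. Under every other alternative as well, 4 of the 20 stayed called.

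In groups, mature neutrophil genes rose in Ezh1-null cells, with 11 of 19 called (16 adjusted over the list alone) and a median of 2.86, as in Cebpe, a regulator of granulocyte maturation (5.06 ± 0.57), and S100a8 (4.86 ± 0.72). Camera gave adjusted p = 6.06e-07, and adjusted p = 0.86 with an estimated correlation. Of 10 primary granule genes 9 rose over all genes (9 higher and 1 lower adjusted over the list alone), with a median of 1.92 (camera adjusted p = 2.93e-05, adjusted p = 0.653 with an estimated correlation). Of 16 B cell genes 9 rose on either adjustment (9 adjusted over the list alone), with a median of 3.71, at camera adjusted p = 0.000671 and adjusted p = 0.86 with an estimated correlation. Erythroid genes had 3 of 15 called (1 adjusted over the list alone) and a median of 2.40, at camera adjusted p = 0.00256 and adjusted p = 0.917 with an estimated correlation. Ribosome biogenesis genes fell, with 5 of 20 called (7 adjusted over the list alone), a median of -0.43 and Rrp12 at -0.86 ± 0.17, at camera adjusted p = 0.00113 and adjusted p = 0.917 with an estimated correlation, and the median was -0.27 without Ezh1-present oil replicate 2.

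Stromal and endothelial genes fell in oil with a median of -1.39 and 3 of 18 called (2 adjusted over the list alone), among them Pdgfrb and Cdh5, at camera adjusted p = 0.0204 and adjusted p = 0.86 with an estimated correlation. This call ended at 0.0752 without Ezh1-null oil replicate 1, with a median of -0.72.

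PRC2 subunits fell as a list in Ezh1-null oil libraries, with 5 of 12 lower and 1 higher over all genes, and 6 lower and 1 higher adjusted over the list alone. Suz12 changed by -0.81 ± 0.10, Aebp2 by -0.57 ± 0.08 and Jarid2 by 0.60 ± 0.15, and the list includes Ezh1 itself. Its camera adjusted p was 0.0391, and adjusted p = 0.653 with an estimated correlation. The PRC2 call ended at 0.0536 without Ezh1-present oil replicate 2, 0.0628 without either Ezh1-present tamoxifen library, 0.0752 without Ezh1-null oil replicate 1 and 0.05 without either Ezh1-null tamoxifen library, and at 0.0578 with quantile normalization. Among CDK inhibitors Cdkn2c rose by 1.46 ± 0.20 and Cdkn2d by 0.81 ± 0.20, while Cdkn1b (-0.65 ± 0.14) and Cdkn1a (-0.72 ± 0.17) fell. The calls of Cdkn1a, Cdkn1b and Cdkn2d ended at adjusted p of 0.122, 0.114 and 0.141 without Ezh1-present oil replicate 1, 0.0761, 0.0969 and 0.0746 without Ezh1-null oil replicate 1, and 0.148, 0.121 and 0.158 without replicate 2. Those of Cdkn1a and Cdkn2d ended at 0.128 and 0.126 without Ezh1-present oil replicate 2, those of Cdkn1b and Cdkn2d at 0.0562 and 0.0636 without either Ezh1-present tamoxifen library, and that of Cdkn1a at 0.0517 without either Ezh1-null tamoxifen library. Cdkn2a changed by -0.20 ± 0.20 (adjusted p = 0.515).

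**Figure D4:**
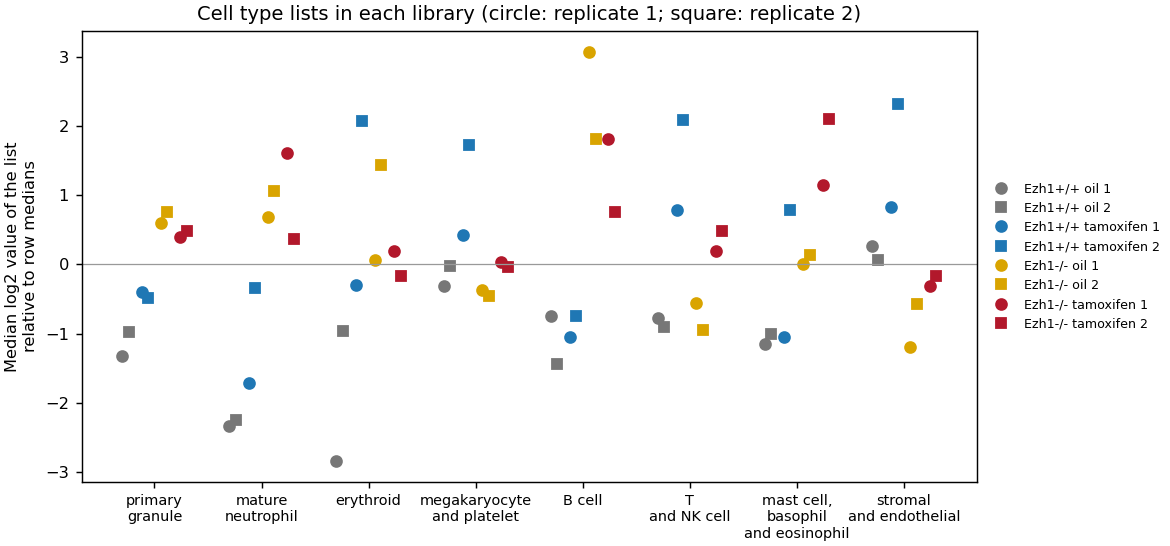
Median log2 value relative to row medians (vertical axis) of 8 cell type lists in each of the 8 libraries. Colours are groups, circles replicate 1 and squares replicate 2. The erythroid list lies at -2.84 in Ezh1-present oil replicate 1 and at 2.07 in Ezh1-present tamoxifen replicate 2, and the B cell list at 3.07 and 1.81 in the Ezh1-null oil libraries.

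The last comparison asks how Ezh1-null cells differ from Ezh1-present ones after tamoxifen. Stefin A genes of chromosome 16 led the rises: BC100530 (7.87 ± 0.69), Stfa2 (7.16 ± 0.85), Stfa2l1 (7.14 ± 1.00), Stfa3 (6.79 ± 0.93) and Stfa1 (6.55 ± 0.69), with BC117090 at least 67.9-fold higher. These genes are close relatives, so reads may not be assigned to the right one. Pitx1 (6.43 ± 1.21) also rose, but its limma adjusted p ranged from 0.0129 to 0.987 over 17 alternatives. The platelet genes Ppbp (-5.65 ± 0.86) and Treml1 (-4.98 ± 0.94), the cytochrome Cyp1b1 (-4.99 ± 0.57), Atp6v0d2 (-4.87 ± 0.42) and Actg2 (-4.84 ± 0.49) fell, and the immune checkpoint receptor Pdcd1, Kng1 and Ldhd were at least 8.39-fold, 10.1-fold and 9.31-fold lower. Cdkn2a was higher by 2.01 ± 0.20 (adjusted p = 0.0111) and Cdkn1c by 1.15 ± 0.19 (adjusted p = 0.0268), and the immediate early genes Fos and Fosb by 2.53 ± 0.14 and 2.79 ± 0.25. Of 15 immediate early and heat shock genes 5 were called higher and 1 lower (6 and 1 adjusted over the list alone), with a median of 0.50. That list had camera adjusted p = 0.0348, and adjusted p = 0.673 with an estimated correlation.

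In this comparison 2204 genes were called, 1222 higher and 982 lower, and 151 of these had a group wholly at the floor. The count was 1101 without either Ezh1-present oil library, 620 and 636 without Ezh1-present tamoxifen replicates 1 and 2, 1323 without either Ezh1-null oil library and 337 and 418 without Ezh1-null tamoxifen replicates 1 and 2. With only the tamoxifen groups in the fit it was 27. BC100530, BC117090, Atp6v0d2 and Pdcd1 stayed called without any 1 library, and Pdcd1 alone of these also with only the tamoxifen groups in the fit. For Pdcd1 the Ezh1-null and for BC117090 the Ezh1-present tamoxifen libraries lie at the floor. The calls of both may owe their stability to that. Cdkn2a had an adjusted p of 0.0513 and 0.0555 without Ezh1-null tamoxifen replicates 1 and 2, with a range of 0.00878 to 0.0724 over 18 alternatives. Cdkn1c had 0.112 and 0.0731 without the same 2 libraries, and 0.0743 and 0.0939 without Ezh1-present tamoxifen replicates 1 and 2.

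Interferon response genes were higher in Ezh1-null than in Ezh1-present cells after tamoxifen, and also in oil. In oil 9 of 25 members were higher and 1 lower (11 and 2 adjusted over the list alone), with a median of 0.64, at camera adjusted p = 0.000825 and adjusted p = 0.86 with an estimated correlation. After tamoxifen, of 25 members 14 rose (18 adjusted over the list alone), with a median of 1.23, and the list had camera adjusted p = 8.42e-09 and adjusted p = 0.601 with an estimated correlation. DNA replication and G1/S genes were lower, with 23 of 23 changes below 0 and a median of -0.38. Of these 5 fell over all genes and 15 adjusted over the list alone, among them Mcm6 (-0.50 ± 0.08), Mcm3 (-0.49 ± 0.09) and the ribonucleotide reductase subunit Rrm1 (-0.54 ± 0.10), at camera adjusted p = 3.3e-07 and adjusted p = 0.395 with an estimated correlation. Ribosome biogenesis genes were also lower, with a median of -0.49 and 3 of 20 called (11 adjusted over the list alone). Camera gave adjusted p = 1.48e-05 for them, and 0.673 with an estimated correlation. Mitosis and G2/M genes were lower (median -0.19, camera adjusted p = 0.0186) and MHC class I genes higher (0.45, 0.0439). Both had adjusted p = 0.694 with an estimated correlation. PRC2 subunits fell again, with 5 of 12 lower (6 adjusted over the list alone), Suz12 at -0.84 ± 0.10 and Aebp2 at -0.66 ± 0.08, at camera adjusted p = 0.00451 and adjusted p = 0.395 with an estimated correlation. The 5 include the targeted genes Ezh1 and Ezh2, and the list was not tested without them.

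Of the marker lists, B cell genes (median 2.11, 7 of 16 higher and 1 lower over all genes and adjusted over the list alone) and primary granule genes (0.91, 6 of 10 higher, 7 adjusted over the list alone) were again higher, at camera adjusted p = 0.0172 and 0.000662, and adjusted p = 0.673 and 0.601 with an estimated correlation. Mast cell, basophil and eosinophil genes (1.62, 3 higher and 1 lower, 7 and 1 adjusted over the list alone) passed at 0.0159, with adjusted p = 0.688 with an estimated correlation. The B cell call ended at 0.0821 without Ezh1-present tamoxifen replicate 1, and the mast cell call at 0.0997 without that library and 0.0635 without Ezh1-null tamoxifen replicate 2, while its median was 2.72 without Ezh1-present tamoxifen replicate 2. Mature neutrophil genes rose with a median of 2.11 and 3 of 19 called (6 adjusted over the list alone), at camera adjusted p = 6.22e-05 and adjusted p = 0.673 with an estimated correlation. Without Ezh1-present tamoxifen replicate 1 the neutrophil median was 1.34. Stromal and endothelial genes fell with a median of -1.67, or -1.36 with 2 members at their bound, and 1 of 18 called (8 adjusted over the list alone), at camera adjusted p = 0.000416 and adjusted p = 0.601 with an estimated correlation. T and NK cell genes fell with a median of -1.20, and 2 of 18 called (2 adjusted over the list alone), Cd4 at -2.98 ± 0.33 and Cd28 at -1.45 ± 0.20. This list had camera adjusted p = 0.00294 and adjusted p = 0.673 with an estimated correlation, and without Ezh1-present tamoxifen replicate 2 its call ended at 0.0803 with a median of -0.52.

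The differences between Ezh1 genotypes were much alike in oil and tamoxifen libraries, which share no library. Of genes called higher with Ezh1 loss 870 were shared, where chance gives 152.25, and of genes called lower 690, where chance gives 122.08. Here too both sets of calls use the same fitted spread per gene, so genes of low spread can be called in both. The chance values do not allow for this. Pearson's r across genes was 0.59. Ezh1 genotype and the leukaemia or animal of origin cannot be separated from these labels, for any of the genes named for Ezh1 loss.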

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

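The tests of transcripts seen in 1 library were chosen after the result was seen for read depth, and written before it was seen for neural markers; the interaction was planned, and the genes with opposite calls were picked out after their values were seen.

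The change after Ezh2 deletion differed between cells with and without Ezh1 for 86 genes, by a test of the difference itself. Among those named, the developmental regulator Otx2 (3.83), the collagen gene Col13a1 (4.90), Chn1 (4.44), Car11 (4.03) and C2cd4c (3.97) had a more positive log2 change without Ezh1. The lymphoid enzyme Dntt (-5.21), Rnase10 (-4.39), the cytokine Il4 (-3.76), Gpr44 (-3.76) and Il17re (-3.13) had a more negative one. In all but Dntt, Rnase10 and Il17re a group lies wholly at the floor, so these differences are fitted values and not measured sizes, and 31 of the 86 genes have no identified floor. None of these 10 stayed called without each library in turn, and leaving out 1 library gave from 17 genes (without Ezh1-present oil replicate 1) to 98 (without Ezh1-present tamoxifen replicate 1).

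Opposite calls in the 2 Ezh1 genotypes were found for 6 genes. Fat1, an atypical cadherin, changed by 1.34 without Ezh1 and -0.94 with it, the kinase Wnk2 by 1.27 and -0.79, the pluripotency marker Fbxo15 by 1.11 and -0.82, Gm5415 by 2.69 and -1.82, and Gm5077 by 2.11 and -2.36. Gm6377 went the other way, by -1.73 without Ezh1 and 1.66 with it. They were selected by these calls, so a test of the difference adds nothing for them. With Ezh1-present oil replicate 1 and tamoxifen replicate 2 both left out, limma called 0 genes with Ezh1 present (1914 at an unadjusted p under 0.05) and 0 for the interaction (1857).

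The interaction also passed for 14 gene lists under camera at the preset correlation. The median difference was positive for developmental regulators bound by Polycomb (0.79, from fitted values of which many rest on groups at the floor), interferon response genes (0.66), p53 targets (0.50) and MHC class I genes (0.37). It was negative for erythroid (-3.23), T and NK cell (-1.37), B cell (-1.32), mature neutrophil (-1.24), primary granule (-0.76), stem and progenitor (-0.54) and monocyte genes (-0.33). It was also negative for mitosis (-0.33), cholesterol synthesis (-0.32) and DNA replication genes (-0.30). With an estimated correlation 0 of the 14 passed, and with fry 2. Without 1 library, calls ended for developmental regulators (0.056 without Ezh1-present tamoxifen replicate 1), stem and progenitor genes (0.0754 without Ezh1-present tamoxifen replicate 2), neutrophil genes (0.0553 without the same library) and interferon genes (0.0753 without Ezh1-present tamoxifen replicate 1). They also ended for monocyte genes (0.0586, 0.0846 and 0.0907 without Ezh1-present oil replicate 2, Ezh1-present tamoxifen replicate 1 and Ezh1-null tamoxifen replicate 2) and MHC class I genes (0.0803 and 0.101 without Ezh1-present oil replicate 2 and Ezh1-null oil replicate 2).

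Outside the rows tested, 250 rows lay above the floor in Ezh1-present oil replicate 1 alone, against 58 to 173 in each other library. Greater depth is argued against, since the deepest library, Ezh1-present tamoxifen replicate 1, had 110 such rows. Reads from a neural source stay open as a candidate explanation: of 29 neural markers measured, 31% (9) lay at least 2 log2 units above every other library here, and 0 in each other library. Gpm6a (7.26), Fabp7 (5.84), Gria2 (5.57) and Pou3f2 (5.39) were high, while Metrn (-0.24), Ncam1 (-0.85) and S100b (-0.96) were not, and the c-kit selection should remove such cells. That share lies between the bounds set beforehand, so the test does not decide, and no biological explanation was tested.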

How the results depend on the processing

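The fits with library medians set to 0, with a trend, with rows without an identified floor, and with Ezh1-present oil replicate 1 and tamoxifen replicate 2 both left out were chosen after the data were seen; the others were planned. Upper-quartile scaling and the 2 pseudocounts were not run, since centring removed the levels they need, and the fit without a trend is the one reported. Where a library was left out, the lone library of its group was assumed to vary like the other groups. Such fits have 3 residual degrees of freedom in place of 4, so they have less power. A library of a group not compared acts on the fitted spread alone, and calls lost without it do not rest on its values as an effect. No direction was reversed for the values reported.

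Leaving out 1 library gave 24 to 404 genes for Ezh2 deletion with Ezh1 present, where Cdkn2a lost its call in 7 of 8 fits. It gave 176 to 469 genes without Ezh1, 1707 to 4004 for Ezh1 loss in oil, 337 to 1323 for Ezh1 loss after tamoxifen and 17 to 98 for the interaction. Gene lists called for Ezh2 deletion without Ezh1, among them the interferon and p53 lists, numbered 6 to 15. For Ezh2 itself, Ezh1 loss in oil gave -0.36 to -0.27 and Ezh1 loss after tamoxifen -0.63 to -0.57. Without any 1 library, calls held for 2 of 17, 5 of 19, 17 of 20, 4 of 18 and 0 of 10 named genes in these 5 comparisons in turn.

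With Ezh1-present oil replicate 1 and tamoxifen replicate 2 both left out, limma called 0 genes for Ezh2 deletion with Ezh1 present (1914 at an unadjusted p under 0.05), 240 without Ezh1, 946 for Ezh1 loss in oil, 318 after tamoxifen and 0 for the interaction (1857). Lists numbered 6 with Ezh1 present and 13 without Ezh1, and Ezh2 changed by -0.30 with Ezh1 loss in oil and -0.63 after tamoxifen. With only the groups compared the counts were 0 (3152 at an unadjusted p under 0.05), 240, 2531 and 27, with 13 lists for Ezh2 deletion without Ezh1, and Ezh2 at -0.31 and -0.60 for Ezh1 loss. The 240 genes are the same number in both because groups reduced to 1 library add nothing to the spread.

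The replicate block gave 23, 364 and 1179 genes for Ezh2 deletion with and without Ezh1 and for Ezh1 loss after tamoxifen, 5 for the interaction, 17 lists for Ezh2 deletion without Ezh1, and -0.31 for Ezh2 with Ezh1 loss in oil. Replicate numbers do not pair libraries, with correlations of -0.09 to 0.12 between groups.

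The interaction count was also 37 genes with quantile normalization, 8 with a trend, 28 with a stricter filter and 6 with rows without an identified floor. The cause was not tested. Ezh2 after tamoxifen without Ezh1 passed at -0.76 with quantile normalization (adjusted p = 0.0283), -0.47 with the stricter filter and -0.47 with rows without an identified floor, in a range of 0.0283 to 0.205. With Ezh1 loss in oil, Ezh2 no longer passed at -0.29 with quantile normalization, -0.31 with robust moderation and -0.31 with no filter. Without a filter 12 lists passed for Ezh2 deletion without Ezh1. For gene lists, the estimated correlation left 0 called in each of the 5 comparisons. Correlation between members does not alone account for this. The p53 list for Ezh2 deletion without Ezh1 had an estimated correlation of -0.01, below the preset 0.01. Its unadjusted camera p still went from 5.07e-11 to 0.0021, since the estimated form uses the 4 residual degrees of freedom. Fry called 0 for Ezh2 deletion with Ezh1 present, 7 without Ezh1 (CDK inhibitors and fetal genes among them, which camera did not call), 6 and 7 for Ezh1 loss in oil (fetal genes among them, not called by camera) and after tamoxifen, and 2 for the interaction.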

Other observations

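The tests of the B cell list, of leaving out 1 tamoxifen library and of the correlation between Ezh1 comparisons were chosen after the result was seen; those of the chromosome 11 flank and of X-linked genes were written before.

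Some called members of lists that did not pass as a whole are not described above. Among subunits of Polycomb repressive complex 1, some forms of which bind the mark of PRC2, limma called 3 higher and 5 lower in oil. After tamoxifen it called 2 higher and 0 lower (5833 genes there had an unadjusted p under 0.05). Pcgf5 was higher in Ezh1-null cells by 0.90 ± 0.12 in oil and 0.73 ± 0.12 after tamoxifen. Among glycolysis genes 4 were called higher and 1 lower in oil, and 1 and 1 after tamoxifen. Gpi1 was higher by 1.16 ± 0.13 and 0.96 ± 0.13, and Pfkp lower, at -1.21 ± 0.17 and -0.88 ± 0.17.

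Markers of other marrow cells, such as erythroid and T and NK cell genes, were higher after tamoxifen with Ezh1 present by camera at the preset correlation, with 0 members of these 2 lists called by limma over all genes (3713 genes of the comparison had an unadjusted p under 0.05) and adjusted p = 0.558 with an estimated correlation. A lower share of leukaemic cells may raise every other cell type alike, and this stays open. The B cell list had a median of 1.01 (camera adjusted p = 0.0859). The median over the erythroid, megakaryocyte, T and NK and neutrophil lists pooled exceeded that by 0.92 (p = 0.0504 over permutations of genes). Genes of a list vary together, with an estimated correlation of 0.91 for erythroid genes, so this p does not measure the spread between libraries. The lists of mast cell (2.59), stromal (1.29), stem cell (1.22), primary granule (0.53) and monocyte genes (0.22) also passed camera upwards at the preset correlation, each at adjusted p = 0.558 with an estimated correlation. A single tamoxifen library with more such cells may also contribute, since without replicate 2 the list medians were between 0.5 and 0.84 times those with it. The range includes the bound set for it, so the 2 cannot be told apart. The c-kit selection should remove mature erythroid, T and neutrophil cells, but not every cell type that these lists mark. An effect of Ezh2 deletion on differentiation stays open and untested.

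More genes were called for Ezh1 loss than for Ezh2 deletion, among them early B cell genes such as Rag1 and Ebf1. A flanking region of another strain, taken as 10 Mb on either side of Ezh1, holds 330 of the genes tested. Calls outside it numbered 2147 after tamoxifen and 4394 in oil, against 614 for Ezh2 deletion without Ezh1. So few flanking genes could not hold the excess of calls, so the outcome of this test was fixed. Within the region 30% of genes were called in oil and 17.3% after tamoxifen, against 24.8% and 12.1% elsewhere. Effects of flanking genes on genes elsewhere were not tested. Different leukaemias or animals behind the genotypes cannot be told apart from Ezh1 loss, since the design confounds them, and the correlation of 0.59 between the oil and tamoxifen comparisons would follow from either. The order of the counts is not fixed, since with only the groups compared Ezh1 loss after tamoxifen gave 27 genes and Ezh2 deletion without Ezh1 240.

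A separate hypothesis was that X-linked genes, where Polycomb acts in X inactivation, would be over-represented among genes that rose after Ezh2 deletion without Ezh1. They were not, with 14 of 560 (2.5%) against 3.3% of genes tested (one-sided Fisher's exact test, p = 0.898). The sex of the cells was not examined, and male cells have no inactive X, so nothing follows for X inactivation.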
